A study of Mus musculus with 12 samples.

How the data were processed

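Polyadenylated RNA of BV2 cells, selected with oligo-dT, was sequenced in 12 libraries, and 1 table of the whole series was used here, with 27487 genes and, for each library, a column of estimated counts and a column of FPKM. Each column was matched to a library by its name and the labels, and 0 columns of per-sample values were left unmatched. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.4d, edgeR and genome build GRCm39, with no role or order. The annotation release, the strand setting and any filter are not given in the sources used here. The estimated counts were deposited by the authors as whole numbers that were not scaled between libraries, per the file headers and the differing column totals. Low values of these estimated counts pile up at multiples of 4: 33.0% of values from 2 to 41 are such multiples, where an even spread gives 25%. A sequenced fragment thus appears to stand for about 4 units, so the deposited totals of 53512190 to 68316549 overstate the number of fragments. FPKM (fragments scaled to transcript length and library size) were computed by the authors, per the file headers, and the ratio of count to FPKM lay within 2% of a constant per gene and library for 98.4% of values of at least 200 counts.

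Groups and replicate numbers were taken from the labels: CTR, Neu and Neu+NETs, with 4 libraries each. Before the data were examined, the groups, the comparisons, the gene lists, the rule for the genes named and all alternatives except 1 were fixed. That plan assumed a table of FPKM and limma on log2(FPKM + 1), with edgeR if whole-number counts were present. As the table holds whole-number estimated counts, edgeR was used for the main results and limma on FPKM became an alternative. The counts were used as deposited.

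Genes were kept by edgeR's filterByExpr (16387 genes), libraries were scaled by TMM (factors 0.970 to 1.03), and all 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with a mean per group. The common biological coefficient of variation was 12.5%. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and genes with an adjusted p under 0.05 were called. SE is the log2 fold change divided by the square root of F. A count of 3 fragments, or 12 units, was taken as the floor under which an absence is not resolved, and genes near it are given as levels only. Floors cover counting error only.

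There were 30 gene lists. The lists of gene function were inflammatory cytokines and chemokines, NF-kappaB targets, inflammasome and Toll-like receptor signalling, interferon-stimulated genes, cytosolic DNA sensing, homeostatic and disease-associated microglia, alternative activation, angiogenic factors, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, cholesterol synthesis, cholesterol efflux and liver X receptor targets, the integrated stress response, NRF2 targets, lysosome and phagocytosis, antigen presentation, complement, immediate early genes, histones and mitochondrially encoded genes. Other lists held markers of mature neutrophils, neutrophil precursors, monocytes, lymphocytes, erythroid cells, mast cells with basophils and eosinophils, retinal neurons and glia, and endothelial cells and fibroblasts. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 78 tests. Adjusted p of lists are those with the preset correlation unless stated. With an estimated correlation the smallest was 2.4e-05, so the size of the preset values depends on the correlation assumed. GO, KEGG and Reactome terms carried by the deposited table (17685, 343 and 9344 terms) were tested with one-sided Fisher's exact tests against all genes tested, for terms of 10 to 500 genes.

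The rule for named genes took, per comparison, the 10 largest changes in each direction among called genes whose group ranges did not overlap, with a mean FPKM of at least 5 in the higher group and a symbol that is not a clone or predicted-gene name. It added up to 4 called members of each list, those with the smallest adjusted p, and 36 genes named in advance, of which 3 were not analysed here. It gave 227 genes, and those of them that the text names were picked after their values were seen. Aldoa, Irf8 and Spi1 stand outside the rule and were singled out after the values were seen, the last 2 from a set of factors written down before its test. Genes with near-identical copies, such as Selenbp1 and Selenbp2 or members of the Ifi200 and Oas families, can share reads, so their values are uncertain, and the strand setting leaves overlapping and antisense genes uncertain too. There are 162 genes whose symbol stands on more than 1 row.

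Alternatives were limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.5, other filters, other scalings, array weights and no trend; DESeq2 1.42.0; edgeR with other size factors, without a filter, on the 8 libraries compared, with the replicate number as a block and without each library in turn; and a fold threshold. Limma tested the 11626 genes with an FPKM of at least 1 in at least 4 libraries, except where another filter is named. Counts divided by 4 were added after the data were seen. The tests of single genes with edgeR, limma and DESeq2 were tested on simulated counts drawn for the 16387 genes with 200 changed genes, 50 per fold size. At a fold of 2 edgeR recovered 62% of the changed genes in Neu against CTR, 64% in Neu+NETs against CTR and 60% in Neu+NETs against Neu. At a fold of 4 it recovered 78%, 78% and 86%. False calls numbered 2, 15 and 3 (1.65%, 10.7% and 2.34% of calls), and the 10.7% lies above the adjusted p threshold of 0.05. A planted list and a planted term were found in each simulation, with 0 of 25 other lists and 0 of 4316 unrelated terms called. The simulated genes were drawn independently, so false calls of lists or terms whose genes are correlated were not tested. Each comparison had a single simulation of single genes, with nearly all genes unchanged. In the data 45.3% to 62.5% of genes were called, and scaling and error rates with so many changes were not tested. The removal of trends with GC content and length, the divisions of the libraries and the check of pairing had no such test.

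Bias of GC content and transcript length was checked with GENCODE M21 on GRCm38, used for these properties only. The trend was fitted on the 11165 genes with a mean log2 CPM above 1 and removed from 15858 genes with a value. A first version of this check was void, as it left fewer than 80% of the homeostatic list with a value. Coordinates are as deposited, on GRCm39 by the submitters' notes.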

Results

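Polyadenylated RNA of mouse BV2 cells, an immortalised line of microglia (the resident macrophages of brain and retina), was sequenced in 12 libraries, 4 in each of 3 groups. The control group (CTR) held BV2 cells cultured alone, and the Neu group held BV2 cells cultured with primary mouse neutrophils. In the Neu+NETs group the added neutrophils had been stimulated with phorbol myristate acetate (PMA), an activator of protein kinase C that makes neutrophils release extracellular traps (NETs), webs of chromatin and granule proteins. The labels name both a tissue, retina, and a cell line, BV2. The series asks how neutrophils, and their traps in particular, change gene expression in microglia, as part of work on pathological vessel growth in the retina. Each library held 53512190 to 68316549 estimated counts, at an apparent 4 counts per sequenced fragment, and 16387 of the 27487 genes listed passed the filter on low counts. Levels are given as FPKM, mean ± SD of the 4 libraries of a group. Log2 fold changes are given ± SE, with n = 4 libraries per group and the adjusted p of edgeR's quasi-likelihood test (Benjamini-Hochberg, two-sided).

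The 3 groups separated on the first 2 principal components of log2 CPM, which held 40.8% and 15.9% of the variance. On the first component the Neu libraries scored 67.0 to 67.8, the CTR libraries -10.2 to -7.34 and the Neu+NETs libraries -61.1 to -57.2, so the co-culture groups lay on opposite sides of CTR. On the second component CTR scored 42.5 to 50.5 and the 8 co-culture libraries -28.2 to -17.4. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 8.22 to 20.6 over 18 pairs on the counts as deposited and 2.06 to 5.15 on counts divided by 4, the units that a fragment appears to stand for, and each was counted as a sample of its own. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

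**Figure D1:**
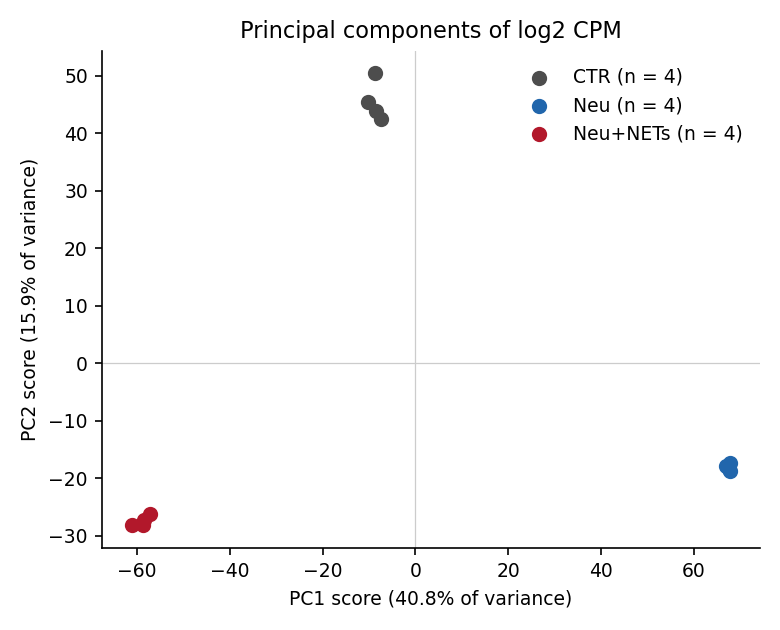
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, without units, with 1 point per library and colours for CTR, Neu and Neu+NETs (n = 4 each). The Neu libraries sit at 67.0 to 67.8 on the first component, opposite the Neu+NETs libraries at -61.1 to -57.2, with CTR between them.

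Cultured with neutrophils, BV2 cells held more transcripts of glucose use and of the response to low oxygen, of inflammatory mediators and of vessel growth factors, and fewer transcripts of DNA replication. Ero1a, an oxidase of the endoplasmic reticulum that is induced when oxygen is low, rose from 19.6 ± 1.35 FPKM in CTR to 261 ± 7.19 in Neu, a log2 fold change of 3.79 ± 0.041 (adjusted p = 3.8e-19). Vegfa, the main growth factor of vessel endothelium, rose 3.97-fold, from 9.57 ± 0.415 to 36.6 ± 1.32 FPKM (log2 fold change 1.99 ± 0.048, adjusted p = 3.3e-15). Nos2, the inducible nitric oxide synthase of activated macrophages, went from 0.183 ± 0.0547 to 95.6 ± 6.31 FPKM (adjusted p = 2.6e-17). Mcm2, a subunit of the replicative helicase, fell from 39.6 ± 0.774 to 12.0 ± 0.223 FPKM (log2 fold change -1.66 ± 0.029, adjusted p = 8.1e-17). In the deposited table, on mouse build GRCm39, the gene span is given for Ero1a (ENSMUSG00000021831) from 45520544 to 45556029 on chromosome 14, minus strand. The same table places Vegfa (ENSMUSG00000023951) from 46327919 to 46343295 on chromosome 17, minus strand, and Mcm2 (ENSMUSG00000002870) from 88860456 to 88875762 on chromosome 6, minus strand. It places Nos2 (ENSMUSG00000020826) from 78811613 to 78851080 on chromosome 11, plus strand.

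Of the 29 tested entries of the glycolysis and hypoxia list (Aldoa stands on 2) 25 rose and 2 fell in Neu, with a median log2 fold change of 0.74. The camera adjusted p was 6.2e-56 with the preset correlation and 7.4e-05 with an estimated one. Ndrg1, a stress gene induced by hypoxia, rose 11.4-fold to 143 ± 4.93 FPKM, the glucose transporter Slc2a1 rose 4.72-fold to 257 ± 11.8, and the phosphofructokinase Pfkp rose 3.39-fold to 100.3 ± 0.901. The transcript of Hif1a itself, the oxygen-regulated subunit of hypoxia-inducible factor, read 31.6 ± 1.38 FPKM in CTR and 31.3 ± 1.83 in Neu (log2 fold change 0.041 ± 0.035, adjusted p = 0.362), and its sign differed between processing settings. Hif1a protein, whose stability oxygen controls, is not measured by RNA sequencing. The largest rises among genes of at least 5 FPKM included Selenbp1, a selenium-binding protein, which went from 5.47 ± 0.716 to 239.9 ± 9.84 FPKM (45.7-fold; reads may be split with its near-identical neighbour Selenbp2), and Tnfrsf9, the co-stimulatory receptor 4-1BB, from 6.38 ± 0.398 to 100.3 ± 2.78 (16.3-fold). The scaffold protein genes Mpp2 and Bcar1, at 0.499 ± 0.119 and 0.356 ± 0.0850 FPKM in CTR, reached 12.3 ± 0.588 and 7.39 ± 0.933.

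Among NF-kappaB targets and inflammatory mediators, 16 of 23 tested genes rose and 4 fell (adjusted p = 1.2e-10). Ptgs2, the inducible cyclooxygenase, rose 10.2-fold to 30.7 ± 0.864 FPKM, Tnfaip3, a feedback inhibitor of NF-kappaB, 5.05-fold to 6.45 ± 0.215, and Acod1, which makes itaconate, 1.71-fold to 209 ± 10.5. The list of inflammatory cytokines and chemokines did not pass (7 of 19 rose, 3 fell, adjusted p = 0.0980; adjusted p = 0.0479 with the replicate number as a block), and its members moved apart. The macrophage inflammatory protein genes Ccl3 and Ccl4 rose 2.66-fold and 2.67-fold (log2 fold changes 1.41 ± 0.036 and 1.42 ± 0.066), and Tnf rose 1.45-fold, while Ccl2, which attracts monocytes, fell 3.13-fold from 112 ± 10.1 to 34.4 ± 2.28. Of 26 immediate early genes 19 rose and 4 fell (adjusted p = 2.8e-06; adjusted p = 0.0756 with an estimated correlation), among them Ier3 (5.59-fold) and Junb (2.08-fold).

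Of 22 tested angiogenic factors 15 rose and 3 fell (adjusted p = 5.5e-07). Beside Vegfa, the urokinase gene Plau rose 1.82-fold to 226 ± 2.38 FPKM and its receptor gene Plaur 2.16-fold to 52.4 ± 2.27. Of 13 cholesterol efflux and liver X receptor targets 8 rose and 2 fell (adjusted p = 2.0e-04), with the desaturase Scd2 up 3.25-fold and the lipid exporter Abca1 up 2.33-fold.

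Of 36 cell cycle genes 32 fell and 2 rose in Neu (adjusted p = 3.3e-29, or 2.4e-05 with an estimated correlation, median log2 fold change -0.61). Cdc6, which loads the helicase onto origins, fell 3.52-fold to 3.91 ± 0.256 FPKM, the helicase subunit gene Mcm6 fell 2.06-fold and Mcm3 had a log2 fold change of -1.32 ± 0.025, and the proliferation marker Mki67 fell 1.51-fold. Outside that list Tfrc, the transferrin receptor of iron uptake, fell 4.05-fold, from 57.4 ± 2.30 to 13.6 ± 0.312 FPKM. By one-sided Fisher tests of annotation terms, 93 of 112 genes of ribosome biogenesis (adjusted p = 5.3e-31), 85 of 107 of DNA replication (adjusted p = 7.1e-26) and 74 of 90 of mitochondrial translation (adjusted p = 3.5e-24) were called lower. Higher calls gathered in calcium ion binding (155 of 327, adjusted p = 3.3e-13), actin binding (135 of 277, adjusted p = 1.0e-12) and focal adhesion (77 of 148, adjusted p = 1.2e-08).

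Smaller shifts passed with the preset correlation but not with an estimated one. Antigen presentation genes were higher on balance (12 of 20 rose, 1 fell, adjusted p = 0.0122; adjusted p = 0.122 with an estimated correlation), with Cd74, the invariant chain of class II molecules, up 2.69-fold. Genes of disease-associated microglia went both ways (11 of 23 rose, 5 fell, adjusted p = 0.0161; adjusted p = 0.0867 with an estimated correlation), and Lpl (lipoprotein lipase) and Lgals3 (galectin 3) rose 1.36- and 1.68-fold. Of 34 oxidative phosphorylation genes 20 fell and 2 rose (adjusted p = 0.0258; adjusted p = 0.563 with an estimated correlation), with Cyc1, cytochrome c1, down 1.62-fold. Of 23 NRF2 targets 14 fell and 5 rose (adjusted p = 0.0167; adjusted p = 0.132 with an estimated correlation): the thioredoxin reductase Txnrd1 fell 1.82-fold, while the heme oxygenase Hmox1 rose 3.33-fold.

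The lists of interferon-stimulated genes (6 of 36 rose, 18 fell, adjusted p = 0.142), cytosolic DNA sensing (5 of 17 rose, 5 fell, adjusted p = 0.483) and homeostatic microglia genes (3 of 16 rose, 4 fell, adjusted p = 0.501) did not pass in Neu. Within them the antiviral gene Oasl1 fell (log2 fold change -0.58 ± 0.038) and the signal transducer Stat2 rose 1.71-fold, and Cgas, the sensor of cytosolic DNA, fell 2.27-fold from 12.8 ± 0.394 to 5.42 ± 0.289 FPKM. Sting1, the adaptor that acts after Cgas, read 20.4 ± 1.19 and 20.4 ± 0.104 FPKM (adjusted p = 0.287). Csf1r, the receptor for colony-stimulating factor 1, read 91.3 ± 2.99 and 87.9 ± 2.84 FPKM (adjusted p = 0.972), with a log2 fold change of 0.0015 ± 0.031 whose sign differed between settings. The fractalkine receptor Cx3cr1 rose from 0.718 ± 0.191 to 5.48 ± 0.179 FPKM (adjusted p = 1.1e-08).

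Markers of neutrophils moved with these groups. Of 14 tested mature neutrophil markers 7 rose and 0 fell (adjusted p = 0.0167; adjusted p = 0.0509 with an estimated correlation), and of 6 precursor markers 5 rose and 1 fell (adjusted p = 4.7e-04). BV2 cells express several of these genes themselves, Acod1 among them, and 19 of the markers stayed under 1 FPKM in every CTR library. In Neu the most abundant of those 19 was the decoy receptor Il1r2, at 8.03 ± 0.302 FPKM, while S100a8, the calprotectin subunit that mature neutrophils carry in large amounts, stood at 0.189 ± 0.0455 against 0.257 ± 0.249 in CTR. The granule enzyme genes Mpo and Elane stood at 0.00219 ± 0.00438 and 0.0969 ± 0.0827 FPKM in Neu. S100a9, Ly6g and Padi4 were not analysed here, and whether neutrophils were removed before RNA was taken is not given in the sources used here.

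In total 4284 genes were called higher and 4578 lower in Neu than in CTR by edgeR's quasi-likelihood test at an adjusted p under 0.05. Of these, 1086 and 408 differed by at least 1 on the log2 scale, and the ranges of the 2 groups did not overlap for 3483 and 4330. Called genes were picked for differing between the groups, so separate ranges among them are no further evidence. With limma on log2(FPKM + 1), which tested 11626 genes, 3180 were higher and 5045 lower, a higher share of 38.7% instead of 48.3%. That share was 44.6% with limma on all 27487 genes and 46.0% after median-of-ratios scaling. It thus moved with the genes tested and the scaling. Of 26 lists tested, 12 passed with the preset correlation and 6 of these with an estimated one.

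**Figure D2:**
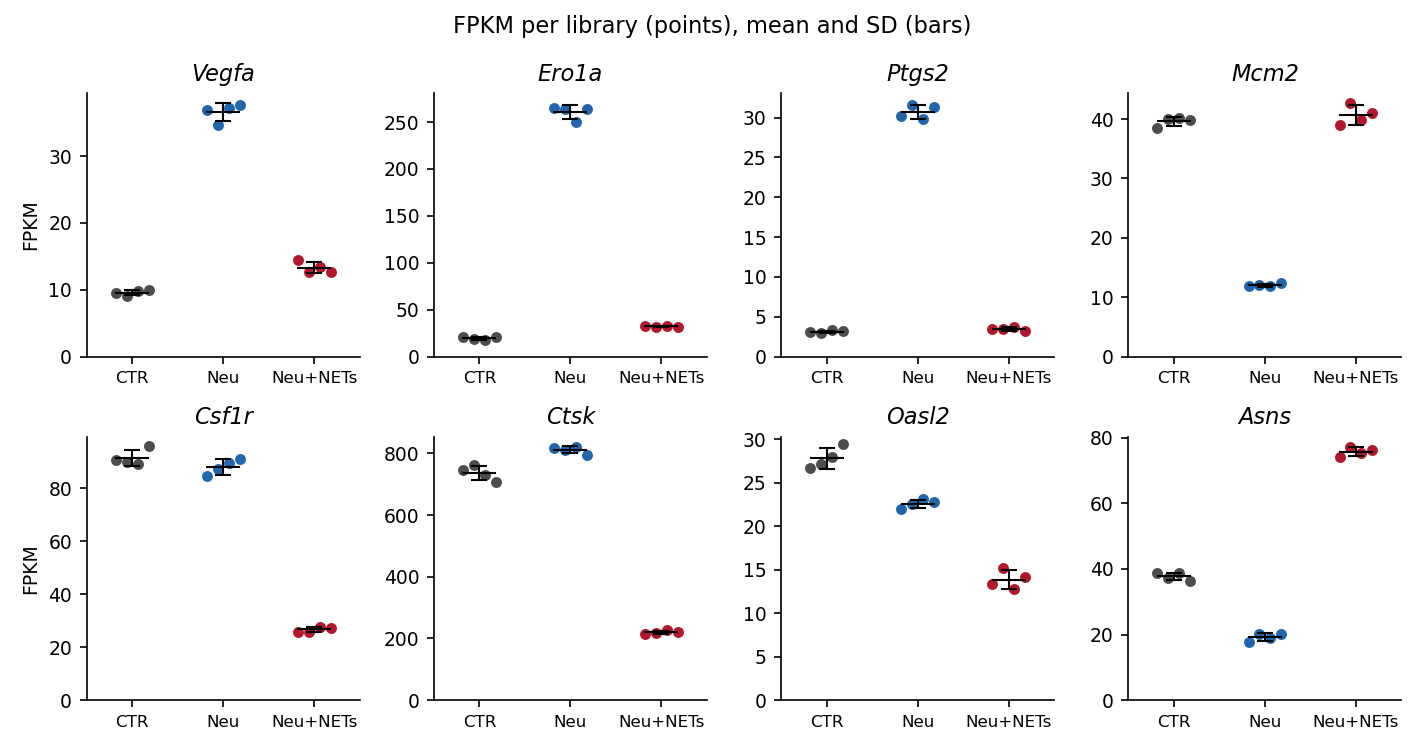
FPKM (vertical axes, each from 0) of 8 genes in CTR, Neu and Neu+NETs, with 1 point per library, the mean as a horizontal line and ± SD as bars (n = 4 each). Vegfa, Ero1a and Ptgs2 stand highest in Neu and Mcm2 lowest there, Csf1r, Ctsk and Oasl2 stand lowest in Neu+NETs, and Asns reaches 75.8 ± 1.31 FPKM in Neu+NETs.

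Cultured with PMA-stimulated neutrophils, BV2 cells held fewer transcripts of microglial receptors, lysosomal enzymes, interferon-stimulated genes, complement and innate immune receptors than BV2 cells alone, and more transcripts of the integrated stress response. Csf1r, on which microglia depend for survival, fell from 91.3 ± 2.99 to 26.7 ± 0.994 FPKM (log2 fold change -1.82 ± 0.033, adjusted p = 1.4e-16). Ctsk, the lysosomal protease cathepsin K, fell from 736 ± 24.0 to 219 ± 5.45 FPKM (log2 fold change -1.80 ± 0.030, adjusted p = 6.1e-17). Acod1 fell 17.8-fold, from 128 ± 3.95 to 7.41 ± 0.536 FPKM (adjusted p = 1.5e-18). Asns, the asparagine synthetase gene that amino acid stress induces, rose from 37.8 ± 1.14 to 75.8 ± 1.31 FPKM (log2 fold change 0.95 ± 0.036, adjusted p = 1.6e-12). On GRCm39 the deposited table places Csf1r (ENSMUSG00000024621) from 61233670 to 61264206 on chromosome 18, plus strand. It lists Ctsk (ENSMUSG00000028111) from 95406567 to 95416673 on chromosome 3, plus strand, and Asns (ENSMUSG00000029752) from 7675169 to 7693254 on chromosome 6, minus strand. Its columns give Acod1 (ENSMUSG00000022126) from 103284413 to 103294009 on chromosome 14, plus strand.

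Of 16 tested homeostatic microglia genes 15 fell and 0 rose (camera adjusted p = 1.4e-18, or 3.1e-04 with an estimated correlation, median log2 fold change -1.54). Tmem119, a microglial surface protein, fell 3.75-fold to 1.01 ± 0.0703 FPKM, the integrin subunit Itgam 2.02-fold and the protease inhibitor Cst3 1.95-fold. Genes of disease-associated microglia fell as well, 19 of 23 with 3 rising (adjusted p = 4.7e-34). Gpnmb, a transmembrane glycoprotein, fell from 989.7 ± 11.8 to 390.3 ± 11.3 FPKM, Apoe, the lipid carrier apolipoprotein E, from 528 ± 13.0 to 263 ± 8.97, Lpl from 79.3 ± 1.67 to 44.0 ± 0.579, and Igf1, insulin-like growth factor 1, 9.34-fold to 0.536 ± 0.0331. Spp1, the gene of the secreted protein osteopontin, fell 1.22-fold, to 1125 ± 34.1 FPKM.

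Of 30 lysosome and phagocytosis genes 28 fell and 1 rose (adjusted p = 7.7e-34, or 4.0e-04 with an estimated correlation, median -0.72). The high-affinity antibody receptor Fcgr1 fell 3.47-fold to 13.5 ± 0.743 FPKM, and the protease genes Ctsd and Lgmn fell 1.78-fold and 1.92-fold. On no fixed list, Siglec1 and Cd33, receptors for sialic acid, fell 7.87-fold and 7.40-fold. Of 13 cholesterol efflux and liver X receptor targets 10 fell and 0 rose (adjusted p = 7.3e-08), with Abca1 down 7.53-fold. Of 14 alternative activation genes 12 fell and 0 rose (adjusted p = 2.1e-05), among them the interleukin 1 receptor antagonist Il1rn, down 2.81-fold. Of 17 complement genes 13 fell and 0 rose (adjusted p = 8.7e-08), with C3 down 3.93-fold to 5.09 ± 0.404 FPKM.

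Of 36 interferon-stimulated genes 34 fell and 0 rose (adjusted p = 1.3e-15, median -0.61). The 2'-5'-oligoadenylate synthetase family genes Oasl1, Oasl2 and Oas2 fell 1.89-, 2.07- and 1.80-fold, Isg15, a ubiquitin-like modifier, fell from 97.6 ± 9.45 to 60.9 ± 1.76 FPKM and the transcription factor gene Irf7 from 81.7 ± 2.45 to 61.1 ± 2.25. Of 17 genes of cytosolic DNA sensing 12 fell and 4 rose (adjusted p = 8.4e-09). In that list the DNA-binding protein gene Ifi204 fell 2.40-fold, while Cgas rose 1.15-fold to 15.2 ± 0.845 FPKM (adjusted p = 0.00381). Sting1 read 20.6 ± 0.928 FPKM (log2 fold change -0.033 ± 0.043, adjusted p = 0.591), with a sign that differed between settings. Of 20 antigen presentation genes 15 fell and 1 rose (adjusted p = 6.8e-09), with the immunoproteasome subunit Psmb8 down 1.61-fold and the co-stimulatory ligand Cd86 down 2.19-fold.

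Of 27 genes of inflammasome and Toll-like receptor signalling 20 fell and 2 rose (adjusted p = 1.2e-10). Tlr13, a sensor of bacterial ribosomal RNA, fell 4.63-fold to 11.3 ± 0.962 FPKM, Tlr9, a sensor of unmethylated DNA, 2.95-fold to 1.83 ± 0.353, Tlr2 2.15-fold and Tlr4, the endotoxin receptor, 1.52-fold, while Nlrp3 rose 1.16-fold (adjusted p = 1.1e-04). Of 23 NF-kappaB targets 18 fell and 2 rose (adjusted p = 1.2e-16), among them Slfn2, down 4.90-fold, and Ptgs2 read 3.44 ± 0.245 FPKM against 3.14 ± 0.135 in CTR (adjusted p = 0.199, and 0.0407 without Neu+NETs replicate 4). The chemokine genes Ccl3 and Ccl4 rose in this comparison too, Ccl3 3.70-fold to 964 ± 32.9 FPKM and Ccl4 2.43-fold to 136 ± 10.9, while Tnf rose 1.24-fold and Ccl2 fell 2.81-fold. The list of 19 inflammatory cytokines and chemokines held 6 rising and 10 falling genes and did not pass (adjusted p = 0.507), with a median log2 fold change of -1.33 and a mean of -0.91, although the test statistic leaned upwards.

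Of 29 genes of the integrated stress and unfolded protein response 21 rose and 4 fell (adjusted p = 2.2e-09, median log2 fold change 0.45). Beside Asns, the mitochondrial one-carbon enzyme genes Aldh1l2 and Mthfd2 rose 3.47-fold and 1.77-fold and Trib3, a pseudokinase of the response, 2.71-fold to 16.9 ± 0.498 FPKM. Of these 3 genes, Aldh1l2 and Trib3 were not particular to Neu+NETs: Trib3 stood at 15.3 ± 0.558 FPKM in Neu and 6.02 ± 0.630 in CTR, and Aldh1l2 rose more in Neu, 6.81-fold to 10.1 ± 0.614 FPKM, and was 1.96-fold lower in Neu+NETs than in Neu (adjusted p = 2.3e-11). Atf3, a transcription factor of the same list, fell 2.22-fold to 11.5 ± 0.480. Of the 29 glycolysis and hypoxia entries 16 rose and 9 fell (adjusted p = 0.00137; adjusted p = 0.107 with an estimated correlation), with Slc2a1 up 1.76-fold and Pfkp up 1.37-fold. Vegfa rose 1.35-fold to 13.3 ± 0.843 FPKM (adjusted p = 9.7e-07) and Hif1a 1.18-fold, but the 22 angiogenic factors went both ways (7 rose, 10 fell, adjusted p = 0.643). Cell cycle genes did not pass as a list (7 of 36 rose, 17 fell, adjusted p = 0.205), and Mki67 fell 1.34-fold. Among single genes, Fosl1, a subunit of the AP-1 transcription factor, rose from 1.84 ± 0.374 to 9.62 ± 2.86 FPKM (log2 fold change 2.33 ± 0.20) and the secreted phospholipase gene Pla2g5 rose 3.40-fold to 33.7 ± 1.84.

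Annotation terms by one-sided Fisher tests held more higher calls than the rest of the genes in ribosome biogenesis (68 of 112, adjusted p = 7.4e-16) and in protein processing in the endoplasmic reticulum (76 of 152, adjusted p = 1.4e-11). Lower calls gathered in immune system process (225 of 399, adjusted p = 5.4e-42), innate immune response (169 of 330, adjusted p = 2.0e-24) and defense response to virus (87 of 167, adjusted p = 6.0e-13). Neutrophil markers fell with the microglial genes: 12 of 14 mature markers fell and 0 rose (adjusted p = 4.3e-18), and S100a8 stood at 0.0547 ± 0.0703 FPKM.

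In all, 3535 genes were called higher and 3885 lower in Neu+NETs than in CTR by edgeR's quasi-likelihood test at an adjusted p under 0.05, 257 and 929 of them by at least 1 on the log2 scale. Among these called genes, group ranges did not overlap for 3290 and 2962. With limma on log2(FPKM + 1), over 11626 genes, the higher share of the calls was 58.5% instead of 47.6%. It was 56.8% with limma on all 27487 genes and 54.1% after median-of-ratios scaling. Of 26 lists 16 passed, 13 of them with an estimated correlation.

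**Figure D3:**
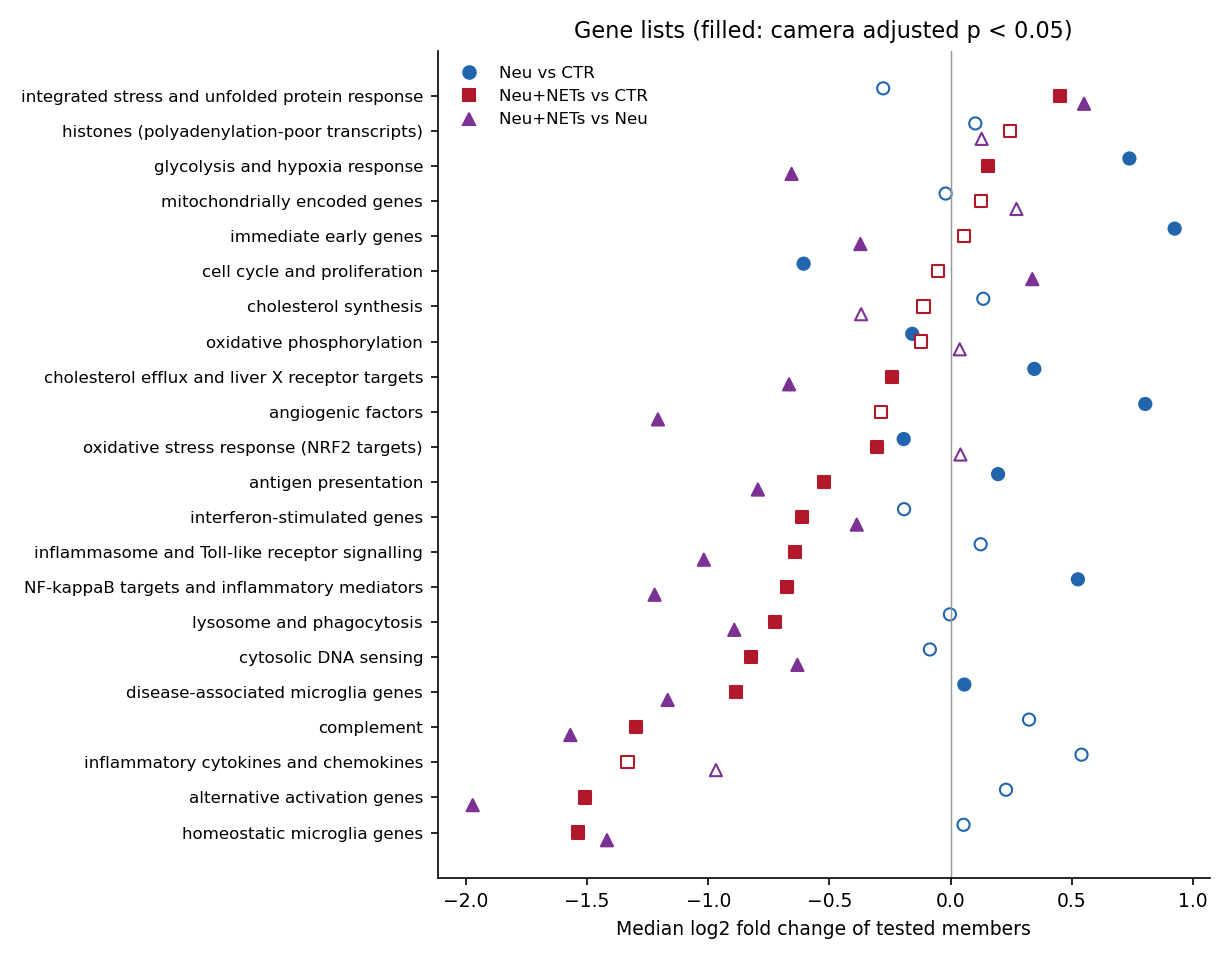
Median log2 fold change (horizontal axis) of the tested members of 22 fixed gene lists (vertical axis), with circles for Neu against CTR, squares for Neu+NETs against CTR and triangles for Neu+NETs against Neu, each filled where the camera test passed at an adjusted p under 0.05 (4 libraries per group). The homeostatic microglia list lies at 0.053 in Neu against CTR and at -1.54 in Neu+NETs against CTR, and the glycolysis and hypoxia list at 0.74 and 0.16.

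Set against unstimulated neutrophils, stimulated neutrophils left BV2 cells with lower hypoxia, inflammatory, lysosomal and microglial transcripts and higher replication and stress-response transcripts. Selenbp1 fell 74.7-fold, from 239.9 ± 9.84 FPKM in Neu to 3.45 ± 0.267 in Neu+NETs (log2 fold change -6.22 ± 0.074, adjusted p = 4.5e-19). Acod1 fell 30.3-fold to 7.41 ± 0.536 FPKM (log2 fold change -4.92 ± 0.051, adjusted p = 1.2e-19). Nos2 stood at 95.6 ± 6.31 FPKM in Neu and at 0.0179 ± 0.0212 in Neu+NETs, where no library held more than 13 estimated counts of it. Tfrc rose 5.94-fold, from 13.6 ± 0.312 to 87.0 ± 2.42 FPKM (log2 fold change 2.57 ± 0.035, adjusted p = 2.0e-18). Both comparisons of Neu+NETs differ by PMA as well as by the traps, and BV2 cells given PMA without neutrophils were not analysed here.

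Of the 29 glycolysis and hypoxia entries 25 were lower and 1 higher in Neu+NETs than in Neu (camera adjusted p = 2.8e-25). Ndrg1, Ero1a and Pfkp were lower by 9.70-, 8.68- and 2.48-fold. Of 22 angiogenic factors 16 were lower and 4 higher (adjusted p = 1.9e-05; adjusted p = 0.0513 with an estimated correlation), with Vegfa lower by 2.95-fold. Of 23 NF-kappaB targets 21 were lower and 2 higher (adjusted p = 5.4e-22), Ptgs2 by 9.58-fold and Slfn2 by 4.56-fold. Of 27 genes of inflammasome and Toll-like receptor signalling 21 were lower and 2 higher (adjusted p = 2.3e-07), Nlrp3 by 2.03-fold and Tlr13 by 6.54-fold. Ccl3 was higher by 1.39-fold. Interferon-stimulated genes were lower in 27 of 36 cases and higher in 2 (adjusted p = 5.4e-04; adjusted p = 0.0977 with an estimated correlation), and genes of cytosolic DNA sensing in 11 of 17 with 4 higher (adjusted p = 0.00693; adjusted p = 0.155 with an estimated correlation), Cgas being 2.60-fold higher.

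The microglial and lysosomal lists were lower against Neu as they were against CTR. Of 16 homeostatic genes 14 were lower and 1 higher (adjusted p = 1.1e-08), with Csf1r lower by 3.54-fold. Of 23 genes of disease-associated microglia 20 were lower and 2 higher (adjusted p = 4.7e-20), Apoe, Lpl and Gpnmb by 2.56-, 2.53- and 2.69-fold. Of 30 lysosome and phagocytosis genes 28 were lower and 0 higher (adjusted p = 2.5e-14), Ctsk by 3.98-fold and Lgmn by 2.04-fold. Complement (14 of 17 lower, 1 higher, adjusted p = 1.5e-04), alternative activation (13 of 14 lower, 0 higher, adjusted p = 0.00184), liver X receptor targets (11 of 13 lower, 0 higher, adjusted p = 2.1e-09) and antigen presentation (16 of 20 lower, 1 higher, adjusted p = 4.6e-08; Cd74 by 3.48-fold) also passed. Neutrophil markers were lower too: 13 of 14 mature markers (adjusted p = 1.9e-11) and 5 of 6 precursor markers (adjusted p = 3.0e-05), with the protease inhibitor gene Serpinb1a falling from 21.4 ± 0.254 to 0.885 ± 0.105 FPKM.

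Of 36 cell cycle genes 28 were higher and 6 lower in Neu+NETs than in Neu (adjusted p = 2.0e-14). Cdc6 was higher by 5.02-fold, Mcm2 by 3.14-fold, Rrm2, a subunit of ribonucleotide reductase, by 4.40-fold, reaching 72.5 ± 1.21 FPKM. The origin recognition gene Orc2, on no fixed list, was 4.63-fold higher. Mcm2 stood at 40.6 ± 1.65 FPKM, beside 39.6 ± 0.774 in CTR. Of 29 stress response genes 22 were higher and 6 lower (adjusted p = 1.5e-05), Mthfd2 by 4.75-fold and Asns by 3.66-fold, with Atf3 lower by 4.78-fold. Of 26 immediate early genes 15 were lower and 6 higher (adjusted p = 0.0133; adjusted p = 0.306 with an estimated correlation).

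Between Neu+NETs and Neu edgeR's quasi-likelihood test called 4819 genes higher and 5422 lower at an adjusted p under 0.05. Of these called genes, 767 and 2085 differed by at least 1 on the log2 scale, and 4683 and 4293 had group ranges that did not overlap. With limma on log2(FPKM + 1), over 11626 genes, the higher share of the calls was 59.9% instead of 47.1%. It was 53.8% with limma on all 27487 genes and 52.8% after median-of-ratios scaling. The median log2 fold change was 0.10 over the 11626 genes with limma and -0.049 over the 16387 genes with edgeR. Of 26 lists 18 passed, 14 of them with an estimated correlation.

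Several fixed lists passed in none of the comparisons or only in part of them. Cholesterol synthesis (adjusted p = 0.0628, 0.705 and 0.0980 in Neu against CTR, Neu+NETs against CTR and Neu+NETs against Neu), histones (adjusted p = 0.667, 0.290 and 0.348) and mitochondrially encoded genes (adjusted p = 0.507, 0.305 and 0.266) did not pass. Monocyte markers (adjusted p = 0.751, 0.0567, or 0.0479 with median-of-ratios scaling, and 0.205) and markers of retinal neurons and glia (adjusted p = 0.681, 0.729 and 0.643) did not pass either. In Neu against CTR the list of inflammasome and Toll-like receptor signalling did not pass (11 of 27 rose, 7 fell, adjusted p = 0.0907), although the inflammasome sensor Nlrp3 rose 2.36-fold. There the lists of alternative activation (6 of 14 rose, 2 fell, adjusted p = 0.426), lysosome and phagocytosis (12 of 30 rose, 9 fell, adjusted p = 0.643), complement (5 of 17 rose, 4 fell, adjusted p = 0.445) and the integrated stress response (8 of 29 rose, 17 fell, adjusted p = 0.285) did not pass. In Neu+NETs against CTR this held for oxidative phosphorylation (0 of 34 rose, 18 fell, adjusted p = 0.0519; adjusted p = 0.0479 with the replicate number as a block) and immediate early genes (10 of 26 rose, 8 fell, adjusted p = 0.09997). In that comparison NRF2 targets passed (5 of 23 rose, 15 fell, adjusted p = 0.00541; adjusted p = 0.0950 with an estimated correlation), as did precursor neutrophil markers (2 of 6 rose, 3 fell, adjusted p = 0.00872; adjusted p = 0.107 with an estimated correlation). In Neu+NETs against Neu the lists of cytokines (3 of 19 higher, 12 lower, adjusted p = 0.422), oxidative phosphorylation (9 of 34 higher, 9 lower, adjusted p = 0.635) and NRF2 targets (9 of 23 higher, 8 lower, adjusted p = 0.845) did not pass. Markers of lymphocytes and of mast cells, basophils and eosinophils had 1 tested gene each, and erythroid and endothelial or fibroblast markers had 4 each, too few for a list test. Of these, 1 erythroid and 2 endothelial or fibroblast markers were called higher and 1 endothelial or fibroblast marker lower in Neu than in CTR. Against CTR, Neu+NETs held 1 lymphocyte marker higher and 1 erythroid and 1 endothelial or fibroblast marker lower. Against Neu it held 1 endothelial or fibroblast marker higher, and 2 erythroid and 2 endothelial or fibroblast markers lower. The mast cell, basophil and eosinophil marker was called in none of them.

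Counts adjusted over the list alone equalled those over all genes tested except in a few lists. In Neu against CTR they gave 14 higher genes of cholesterol synthesis, 9 of liver X receptor targets, 18 lower genes of the integrated stress response, 11 lower lysosomal genes, 5 lower immediate early genes, 5 lower histones and 1 higher lymphocyte marker. In Neu+NETs against CTR they gave 11 lower cytokines, 21 lower genes of Toll-like receptor signalling, 1 higher homeostatic gene, 16 lower NRF2 targets, 18 lower genes of antigen presentation, 11 higher immediate early genes, 4 lower mitochondrially encoded genes, 13 lower mature neutrophil markers, 5 lower monocyte markers and 0 erythroid markers. In Neu+NETs against Neu they gave 22 lower genes of Toll-like receptor signalling, 9 lower NRF2 targets, 6 higher histones and 1 lower erythroid marker. Median and test leaned in different directions, without passing, for histones in Neu against CTR (median 0.10), lysosomal genes in Neu against CTR (median -0.0031) and retinal markers in both comparisons of Neu+NETs (medians -0.042 and -0.071). Median and mean differed in sign for complement (0.32 and -0.23), the integrated stress response (-0.28 and 0.025) and lysosomal genes (-0.0031 and 0.039) in Neu against CTR, and for NRF2 targets (0.040 and -0.082) and retinal markers (-0.071 and 0.024) in Neu+NETs against Neu. In Neu+NETs against CTR the erythroid markers had a median of 0.064 and a mean of -0.017.

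The effects of both kinds of neutrophils were then set side by side. Against CTR, 2355 genes were called in the same direction in Neu and in Neu+NETs and 2884 in opposite directions. Ccl3, Ccl4, Slc2a1, Pfkp and Vegfa rose and Ccl2 and Mki67 fell in both, while Acod1 rose in Neu and fell in Neu+NETs and Cgas fell in Neu and rose in Neu+NETs. By direction, 1135 genes were higher in both, 1220 lower in both, 1349 higher in Neu and lower in Neu+NETs, and 1535 lower in Neu and higher in Neu+NETs. Independent lists of these lengths would share 924, 1085, 1016 and 988 genes. In 20 simulations of unchanged groups against shared controls 0 genes were called in the same direction, but with 0.325 genes called per comparison on average this sets no level for the 2355. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.126, with a covariance of 0.0853. The simulations gave a correlation of 0.503 ± 0.0164 (mean ± SD) and a covariance of 0.0740 ± 0.0041. They hold only the noise of shared controls and no real effects, so their correlation sets no level for the 0.126. With the 4 CTR libraries divided 2 and 2 between the comparisons, 1766 to 1815 genes moved in the same direction and 2313 to 2453 in opposite directions, with a correlation of 0.00834 to 0.0372.

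**Figure D4:**
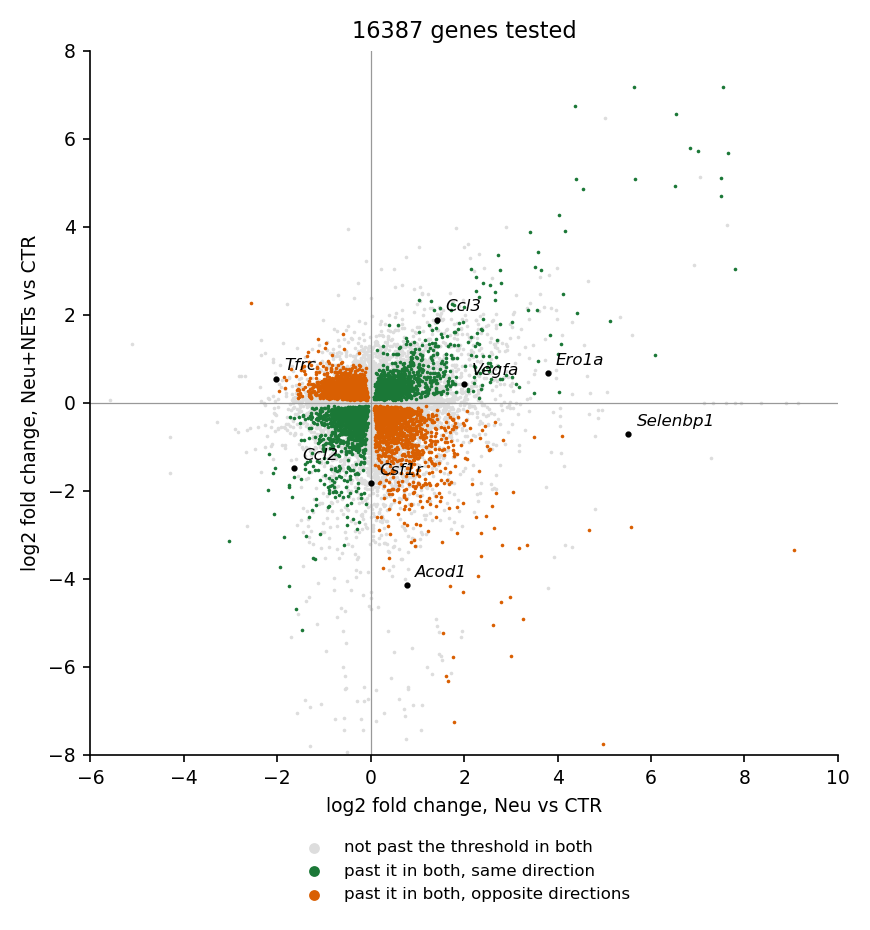
Log2 fold change in Neu against CTR (horizontal axis) and in Neu+NETs against CTR (vertical axis) for 16387 genes, 1 point per gene from 4 libraries per group; 4 genes lie outside the axes. Green points passed in both comparisons in the same direction (2355 genes) and orange points in opposite directions (2884), grey points did not pass in both, and 8 genes carry their names.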

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

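Of the tests in this part, those of neutrophil RNA carried over and of dilution by another cell type were chosen only after the result was seen.

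In groups of 4 libraries, 23 of 270 groups of values held a library whose gap to its nearest neighbour took an unusually large part of the range, where chance gives about 13.5. For each, the gap as a share of the range follows, with the library's value and those of the other 3. Neu replicate 4 held 7 of them, all on the high side: Slc2a1 (0.972, 274 FPKM against 250.3 to 250.9), Selenbp1 (0.958, 255 against 235 to 235.5), Junb (0.926, 173 against 139.8 to 142), Lgals3 (0.914, 657 against 575 to 582), Siglec1 (0.881, 49.1 against 40.8 to 41.7), Ndrg1 (0.879, 151 against 140.2 to 141) and Irf7 (0.838, 85.1 against 75.2 to 76.8). Other Neu libraries stood apart for Ero1a (replicate 3, 0.924, 249.99 against 264 to 265), Cd33 (replicate 2, 0.850, 34.05 against 33.0 to 33.1) and the score on the first principal component (replicate 2, 0.877, 67.0 against 67.7 to 67.8).

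In CTR replicate 2 the share was 0.901 for Acod1 (122 FPKM against 129 to 130.1), 0.863 for Ccl4 (62.0 against 50.6 to 52.2), 0.877 for Ier3 (28.0 against 31.2 to 31.7) and 0.863 for Tlr9 (4.79 against 5.34 to 5.43). CTR replicate 4 stood apart for Atf3 (0.838, 26.5 against 24.0 to 24.4) and Plau (0.845, 123 against 130.3 to 132), and CTR replicate 1 for Lpl (0.859, 81.8 against 78.2 to 78.7). Among Neu+NETs libraries the genes were Atf3 (replicate 3, 0.918, 10.8 against 11.7 to 11.8), Cgas (replicate 1, 0.867, 13.9 against 15.4 to 15.7), Sting1 (replicate 1, 0.964, 19.2 against 21.02 to 21.1), Ier3 (replicate 2, 0.841, 59.2 against 54.2 to 55.0), Pla2g5 (replicate 4, 0.926, 31.0 against 34.5 to 34.8) and Siglec1 (replicate 4, 0.839, 4.93 against 4.18 to 4.30).

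The glycolysis and hypoxia list rose in Neu. Neutrophil RNA carried over is argued against, as 6 abundant neutrophil transcripts together reached 1.33 FPKM in Neu, 0.0484% of the 2740.3 FPKM by which the list rose; a first version, on the sum over 19 neutrophil markers, gave 12.4 FPKM and missed its limit of 10, with 8.03 FPKM from Il1r2. Bias of GC content or length is argued against too, as the list's median was 0.70 after the trend was removed and 0.74 before. Genes annotated to the cellular response to hypoxia and on no fixed list were higher in 44 of 80 cases (55%, against 25.6% of 15778 other genes; odds ratio 3.56, one-sided Fisher's exact p = 2.3e-08), but 21 of the 80 were lower and their median log2 fold change was 0.17. An oxygen-sensing response of BV2 cells in co-culture may thus be a candidate explanation; oxygen was not recorded in the sources used here, and other inducers of these genes stay open.

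The homeostatic microglia and lysosome lists fell in Neu+NETs against CTR. Dilution by another cell type is argued against, as 54 markers of other cells, kept because each stays under FPKM 1 in every CTR library, summed to only 4.00 FPKM in Neu+NETs, and so is scaling, as the median of the 39 members held by the FPKM filter was -0.67 after quantile normalization and -0.73 before, with 35 called lower. Removing the trend with GC content and length left a median of -0.85 over 45 members. A set of macrophage transcription factors, Spi1 and Irf8 among them, was lower in 8 of 8 cases, with a median log2 fold change of -0.91, so their lower levels may be part of the same fall, with no order of events shown. Phorbol ester carried over to BV2 cells cannot be told apart from an effect of the traps, since 0 groups of BV2 cells given phorbol ester without neutrophils were analysed here.

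The cell cycle list fell in Neu against CTR. After the trend with GC content and length was removed its median was -0.59, from -0.61, which argues against that bias as the whole cause. Activation of p53 cannot be told apart from other routes, as 10 tested p53 targets went both ways (5 higher, 3 lower, median 0.20). A change in growth with culture density stays open and was not tested.

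Other divisions of the 8 libraries of a comparison into 4 and 4 were tried, 35 in each comparison. For the numbers of genes, only the real division gave as many (1 of 35 in each direction and comparison), with at most 1 gene otherwise. The real counts were 4284 higher and 4578 lower in Neu against CTR, and 3535 and 3885 in Neu+NETs against CTR. In Neu+NETs against Neu they were 4819 and 5422. First place is the smallest share that 35 divisions can give, and mixing well-separated groups widens the spread and leaves few calls. The counts thus follow the group labels, but this does not exclude chance or a technical difference between groups. The same held for annotation terms (1671, 1630 and 2105, and 0 otherwise). For lists, 1 of 35 divisions, the real division itself, gave as many as the real 12 in Neu against CTR (at most 10 otherwise). For Neu+NETs against CTR 2 of 35 gave as many as the real 17, adjusted within the comparison (at most 18 otherwise), and in Neu+NETs against Neu 8 of 35 as many as the real 18 (at most 21 otherwise). These high counts all came from the 16 divisions that keep 3 of the 4 libraries of a group together, and so hold part of the real difference, with 13 to 18 and 15 to 21 lists. The 18 divisions that mix the groups evenly gave 0 to 2 and 0 to 1 lists, so in these 2 comparisons a high count elsewhere need not come from chance, and the question is left open. In Neu against CTR the 16 divisions that keep 3 libraries together also hold part of the real difference, but gave 2 to 10 lists, all below the real 12. First place among 35 divisions does not exclude chance for those lists either.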

How the results depend on the processing

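Of the tests in this part, the one on counts divided by 4 was chosen only after the result was seen. Over 129 results for single genes, 3442 of 3474 alternative values kept their direction and their side of the threshold. Of the others, 0 lost the call, 5 gained it and 27 changed sign, and these changes fell in 5 results that had not passed. These results are for genes the text names, mostly picked for large changes or small adjusted p. Few of their calls could be lost, so the check does not speak for a typical call. The fold threshold was left out of this check. Calls with an absolute log2 fold change under 1, such as that of Asns in Neu+NETs against CTR, do not meet it. Over all genes, limma on log2(FPKM + 1) shared 7514 of the 8862 edgeR calls in Neu against CTR. It shared 6090 of 7420 in Neu+NETs against CTR and 8071 of 10241 in Neu+NETs against Neu, with 0 called in the opposite direction. Calls not shared include genes that limma did not test. With limma on log2(FPKM + 1), Csf1r in Neu against CTR (0.0015) became -0.054, also with FPKM above 0 in 1 library, with a mean FPKM of at least 5 and without the trend, -0.055 with a pseudocount of 0.1, -0.054 with 0.5 and -0.065 with array weights, and -0.012 to 0.022 without 1 library. Hif1a in Neu against CTR (0.041) became -0.016 under the same settings, pseudocounts included, and -0.037 with array weights. Sting1 in Neu+NETs against CTR (-0.033) became 0.017 under the same settings, and lay between -0.058 and 0.0036 without 1 library, the highest value being that without CTR replicate 4. Quantile normalization gave calls for Sting1 (0.13) and Hif1a (0.11) in Neu and for Ptgs2 in Neu+NETs against CTR (0.11), which also passed with a pseudocount of 0.1 (0.13) and without Neu+NETs replicate 4 (0.13). The cause of these changes was not tested.

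Of the counts, genes lower in Neu+NETs than in Neu (5422) moved to 3581 with limma on log2(FPKM + 1), 3568 and 3580 with pseudocounts of 0.1 and 0.5, and 3584 without the trend. All of these settings tested 11626 genes instead of 16387. Limma on all 27487 genes gave 4776, and limma after median-of-ratios scaling 4195. Limma with a mean FPKM of at least 5, which changes the tool and tests fewer genes, gave 1942 higher in Neu than CTR. It gave 1960 lower in Neu+NETs than CTR and 2172 lower in Neu+NETs than Neu. Its higher shares of calls were 33.3%, 60.5% and 64.7% in the 3 comparisons. Over 11626 genes limma on log2(FPKM + 1) already gave 3180, 2852 and 3581 such genes, with higher shares of 38.7%, 58.5% and 59.9%. Asking also for an absolute log2 fold change of at least 1 gave 1086 higher and 408 lower, 257 and 929, and 767 and 2085 genes in the 3 comparisons, and 153 changed in the same direction in both co-cultures. Enriched terms (5406 over the 3 comparisons) numbered 3138 with limma on log2(FPKM + 1). Other settings of limma gave 3087 and 3137 with the pseudocounts, 2198 with the mean FPKM and 3261 after median-of-ratios scaling. They gave 3211 after quantile normalization, 3054 with array weights and 3043 without the trend. With edgeR, median-of-ratios size factors gave 5424 terms, so this change of scaling by itself did not lower the number. With edgeR and the fold threshold the terms numbered 634. EdgeR on counts divided by 4, which tested 13360 genes instead of 16387, gave 3757 terms, so lower numbers were not confined to limma. The number of terms rose to 10528 with limma on FPKM above 0 in 1 library, 11345 with edgeR without a low-count filter and 11562 with DESeq2, run unfiltered. These 3 settings tested all 27487 genes instead of 16387. Genes with few or no counts thus widened the background, against which terms of expressed genes pass more easily. How much of the rise this makes up, and the cause of the lower counts, were not tested. Over the 11626 genes of limma, deposited FPKM had a median log2 fold change of -0.082, 0.049 and 0.10 in the 3 comparisons. Median-of-ratios scaling of the same genes gave -0.029, 0.026 and 0.027. The 16387 genes of edgeR with TMM had medians of 0.020, 0.00021 and -0.049, but over a different set of genes, so these do not compare scaling alone.

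Leaving out 1 library gave 3981 to 4358 higher and 4339 to 4571 lower genes in Neu against CTR, 3272 to 3589 and 3663 to 3956 in Neu+NETs against CTR, 4636 to 4871 and 5133 to 5467 in Neu+NETs against Neu, 2193 to 2382 shared genes and 5464 to 5816 terms. With the replicate block the counts were 4270 and 4554, 3491 and 3819, and 4793 and 5415, with 2326 shared genes, 5423 terms and 48 of 78 lists, 46 kept and 2 gained (cytokines in Neu and oxidative phosphorylation in Neu+NETs, each against CTR), and 47 with median-of-ratios scaling, 1 gained (monocyte markers in Neu+NETs against CTR). The numbers do not pair the libraries, as same-numbered libraries correlated at -0.11 to 0.077 over 12 pairs, 0 of them above 0.1, and 1 library fitted best with its own number. Counts divided by 4 gave 4375 and 4441, 3637 and 3735, and 4688 and 5210. Of 78 list tests 46 passed with the preset and 33 with an estimated correlation, 13 lost and 0 gained. Depth limits genes near 12 units in a library, such as Nos2 in Neu+NETs, for which only levels are given.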

Other observations

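Annotation terms not described above separated the co-cultures further, by one-sided Fisher's exact tests adjusted by Benjamini-Hochberg. In Neu against CTR, genes of mRNA processing (217 of 342, adjusted p = 1.0e-39), nucleocytoplasmic transport (86 of 102, adjusted p = 9.7e-30) and DNA repair (216 of 365, adjusted p = 3.0e-33) were called lower. The same terms were called higher in Neu+NETs against Neu: 225 of 342 genes of mRNA processing, 92 of 102 of nucleocytoplasmic transport and 214 of 365 of DNA repair (adjusted p = 3.5e-41, 8.2e-35 and 6.4e-29). Genes of tRNA processing were also higher there (72 of 100, adjusted p = 2.5e-16). Both comparisons use the same Neu libraries, so a fall in Neu by itself gives higher calls in Neu+NETs against Neu. Values of these terms in Neu+NETs against CTR are not given here. The HIF-1 signalling pathway, which shares genes with the glycolysis and hypoxia list, was called higher in Neu against CTR (51 of 90, adjusted p = 1.8e-07).

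In Neu+NETs against CTR, genes of protein turnover and synthesis stood on the higher side: 39 of 61 genes of the proteasome complex (adjusted p = 9.7e-10) and 35 of 54 of translational initiation (adjusted p = 2.8e-09). Lower calls gathered in osteoclast differentiation (72 of 116, adjusted p = 7.6e-16), a pathway of the macrophage lineage, in the phagosome (62 of 115, adjusted p = 3.7e-10) and in chemokine signalling (74 of 132, adjusted p = 4.9e-13). The broader annotation of the lysosome, with 349 genes, held 152 higher genes in Neu against CTR (adjusted p = 8.8e-10) and 164 lower genes in Neu+NETs against CTR (adjusted p = 1.2e-18). The share of estimated counts held by the 10 most abundant genes was 6.18% in CTR, 6.49% in Neu and 5.46% in Neu+NETs, and that of mitochondrially encoded genes 2.87%, 2.79% and 2.94%.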
